A study of Mus musculus with 8 samples.

How the data were processed

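RNA from the tibialis anterior of 8 male mice, 4 Prep1f/+ and 4 Prep1deltaSM, was labelled with Cy3 and hybridised to Agilent arrays of design 014868, 1 array per mouse. Per the file headers, the deposited intensity of each spot (gProcessedSignal) was made by Feature Extraction 10.5.1.1 with protocol GE1_107_Sep09, which subtracts background and removes spatial trends without normalizing between arrays; the submitters' processing notes name Agilent Feature Extraction 9.1, and which of these made the values was not settled. The authors also deposited a table of 32812 processed intensity values per array. Set against the scanner values, this table was found to be linear, quantile-normalized and not centred, with column medians of 12.7 to 13.2; 26226 rows lay within 0.1 log2 of the quantile-normalized scanner values on all arrays and were used for an alternative, and how other rows were collapsed over probes stays unknown.

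The log2 intensity of each non-control spot was taken relative to the 75th percentile of its array. Spots flagged as non-uniform, 0 to 11 per array, were set missing, and spots of one probe were averaged. No spot was saturated. Probes well above background on at least 4 of the 8 arrays were kept, 24488 of 41174, and a gene was represented by its brightest probe, which left 16016 genes. Of these, 13570 matched a symbol, synonym or accession in the RefSeq table of assembly GRCm38.p6; the names of the array design are printed. Positions are those of the files, in mm9. Well-above-background spots numbered 23787 to 27123 per array, and the 75th percentile of signal was 139 to 197.

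Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes. The 34 gene lists were fixed before the data were examined, and 33 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists, with an estimated correlation and fry as alternatives. The lists were complexes I, II with III and IV, ATP synthase, TCA cycle, fatty acid oxidation, biogenesis regulators, mitochondrial ribosome, glycolysis, insulin signalling, PBC and MEIS factors, Hox genes, slow and fast fibre genes, myogenic regulators, atrophy, neuromuscular junction, clock, immediate early, stress response, p53, interferon, proliferation, ribosomal protein and calcium handling genes, and markers of adipocytes, endothelium, fibroblasts, tendon, leukocytes, smooth muscle, satellite cells, Schwann cells and erythroid cells. Genes were named by a rule fixed in advance: Pknox1, the 10 genes per direction past the threshold with the largest change, filled with the smallest p where fewer passed, a set of regulators and myosins, and up to 4 members of described lists; 1 gene of that set is not reported here.

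Alternatives were normexp with an offset of 50 on mean signal followed by quantile normalization, quantile normalization alone, median centring, other filters and probe rules, the authors' values, slide as a block, a trended robust fit, array weights, flagged spots kept and each array left out. All arrays were scanned on 1 day, so scan date was not used. The labels do not pair mice across groups. In simulated data with the means and spreads of the 16016 genes, with 200 genes changed, the fit recovered 31.3% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 77.3% of those changed 3-fold, with 4 false calls. The simulated noise was normal and independent between genes, unlike the correlated genes of these data. The shares also depend on the number of genes changed, so they are not the power of the comparison itself.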

Results

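The data were single-colour microarray measurements of RNA from the tibialis anterior, a fast muscle of the lower leg, of male C57BL/6 mice aged 8 weeks. Prep1deltaSM mice (n = 4), in which the Prep1 gene was ablated in skeletal muscle, were set against Prep1f/+ mice (n = 4), which carry a floxed allele. Prep1 is the protein name of Pknox1, a homeodomain transcription factor of the TALE class that acts together with Pbx proteins. The comparison asks what loss of the factor does to the transcriptome of the muscle. Each array carried 43379 non-control spots, of which 23787 to 27123 were well above background. Each of the 4 slides held 1 array of each group, and the number of arrays limits the precision of every value below.

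Pknox1 transcript was 3.39-fold lower in Prep1deltaSM muscle. The normalized log2 signal was -0.28 ± 0.18 (SD, n = 4) in Prep1f/+ and -2.04 ± 0.19 (SD, n = 4) in Prep1deltaSM, a difference of -1.76 ± 0.13 (SE), with a 95% confidence interval of -2.05 to -1.47. The signal that remained was 29.5% of that in Prep1f/+, and the probe stayed well above background on all 8 arrays. All 4 Prep1deltaSM values lay below all 4 Prep1f/+ values (exact two-sided permutation p = 0.0286 over 70 assignments, the smallest that these can give). Here and for the lists below, the assignments take no account of the slides. The adjusted p over all genes was 0.0072 by limma. The only Pknox1 probe of the array (A_52_P431894) lies on chromosome 17 from 31744266 to 31744325 in mm9, the build of the files; its place in the exons or the UTR, and whether it lies in the deleted part of the gene, was not settled here. Within slides 1 to 4 the difference was -1.54, -1.87, -1.87 and -1.77. With slide as a block the adjusted p was 0.062. The difference was -0.89 with normexp background correction at an offset of 50, followed by quantile normalization of mean signal. That alternative changes all of these at once.

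**Figure D1:**
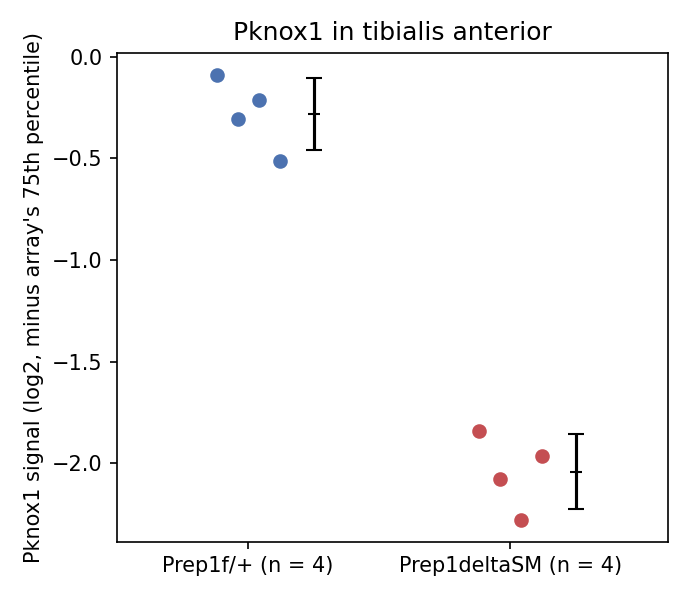
Normalized Pknox1 signal (log2, relative to the 75th percentile of each array) in each of the 8 muscles, with the group mean and SD in black beside the points. The 4 Prep1deltaSM muscles lie between -2.28 and -1.84, all below the Prep1f/+ muscles, which lie between -0.51 and -0.09.

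Across the transcriptome, Pknox1 was the 1 gene of 16016 tested that passed an adjusted p of 0.05 (limma), and 0 genes were higher at that threshold. At an unadjusted p under 0.05 there were 2541 genes, 887 higher and 1654 lower, where 800.8 are expected by chance; under 0.01 there were 328 higher and 441 lower. That balance turned with quantile normalization alone (416 higher and 354 lower) or after normexp (460 and 431), with the authors' values (322 and 251), with every probe as its own row (962 and 525) and with the mean of a gene's probes (392 and 377). The median difference of all genes was -0.07, and the medians and counts of lists given below include that offset. The groups did not overlap for 1675 genes, 10.46% of those tested, where chance gives 2.86%. The next gene had an adjusted p of 0.0897. The genes named next, apart from Pknox1, did not pass in this fit, though some passed under other settings. Without Prep1deltaSM replicate 4, 5 genes were lower at the threshold, and without Prep1f/+ replicate 2, Prep1f/+ replicate 3 or Prep1deltaSM replicate 2 there were 0; without Prep1f/+ replicates 1 and 4, which stand apart on the first principal component, there were also 0.

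The smallest p-values among genes with higher signal in Prep1deltaSM belonged to Btbd9, which lies within 5 Mb of Pknox1, with a log2 difference of 0.83 ± 0.10 (SE), the ubiquitin ligase gene Arih2 with 0.80 ± 0.12, the long noncoding RNA 2900097C17Rik (Norad in the reference names) with 0.65 ± 0.10 and the calpain protease gene Capn2 with 0.57 ± 0.09, each at an adjusted p of 0.0897. Glmn (0.53), the peroxisomal fatty acid transporter gene Abcd2 (0.83) and the homeodomain gene Hoxb6 (0.53) had an adjusted p of 0.107. Srp68, a subunit of the signal recognition particle, followed with 0.61, Eid3 with 0.94 and Nckap1, a subunit of the WAVE complex, with 0.51. With quantile normalization after normexp the differences shrank to 0.35 for Arih2, 0.20 for Glmn, 0.50 for Abcd2, 0.18 for Eid3 and 0.22 for Nckap1. Arih2 and Abcd2 nevertheless passed in that setting (limma adjusted p = 0.0498 and 0.0398). Btbd9 (0.0231), 2900097C17Rik (0.0306), Capn2 (0.0308), Hoxb6 (0.0292) and Srp68 (0.0465) also passed in it. Glmn, Eid3 and Nckap1 did not pass under any alternative setting. Other probes of Btbd9, Abcd2 and Hoxb6 did not share the difference: the lowest was -0.01 for Btbd9, -0.02 for Abcd2 and -0.20 for Hoxb6.

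Among genes with lower signal and a match in the reference table, the smallest p-values after Pknox1 belonged to the centrosomal gene Azi1 (Cep131 in the reference names), with a log2 difference of -0.64 ± 0.08 (SE), Dnajc17 with -0.58 ± 0.08, and Rmrp, the RNA component of the RNase MRP complex, with -1.10 ± 0.15. The linker histone gene Hist1h1a differed by -0.87, the autophagy gene Uvrag by -0.54, the sodium channel gene Scn2a1 by -1.40 and the small nucleolar RNA Snord33 by -1.10. Cdh15, which encodes the M-cadherin of satellite cells, differed by -0.64 ± 0.10, and AY036118 by -2.29 ± 0.34. All of these had an adjusted p of 0.0897. Another Uvrag probe differed by -0.05 and another Dnajc17 probe by -0.26. With quantile normalization after normexp the differences shrank to -0.33 for Scn2a1, -0.36 for Dnajc17 and -0.53 for Hist1h1a. Dnajc17 and Hist1h1a nevertheless passed in that setting (limma adjusted p = 0.0308 and 0.0306). Azi1 (0.0306), Rmrp (0.0319), Uvrag (0.039) and AY036118 (0.0474) also passed in it, while Scn2a1, Snord33 and Cdh15 did not.

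**Figure D2:**
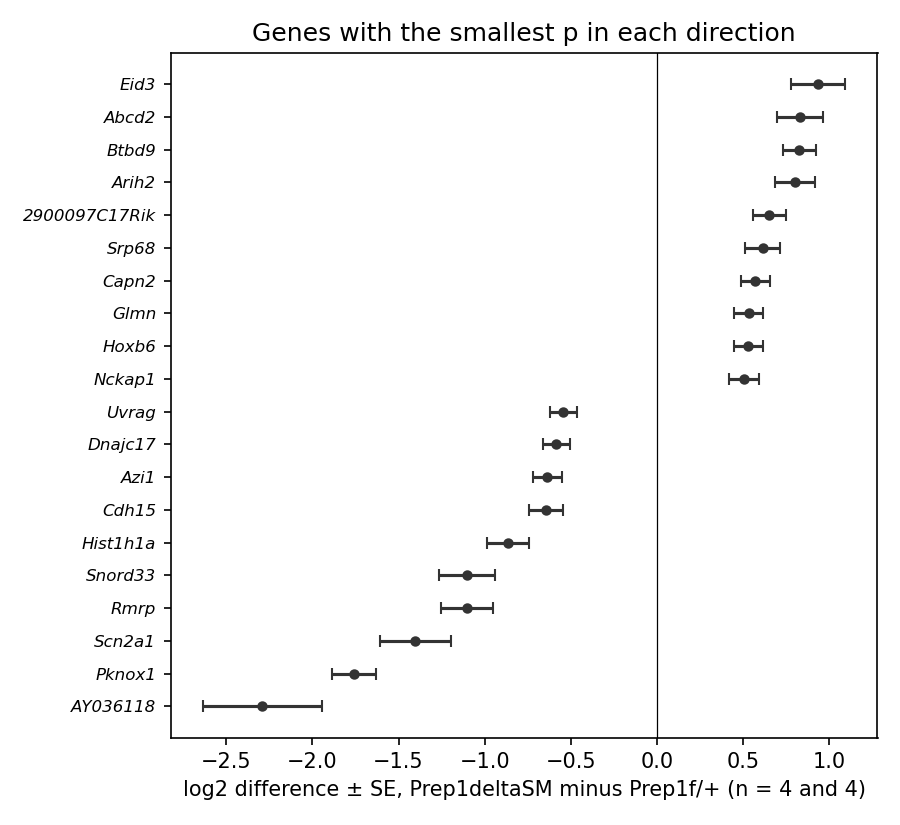
Log2 difference between Prep1deltaSM and Prep1f/+ (x axis, with SE bars, n = 4 and 4) for the genes with the smallest p in each direction among those with a match in the reference table. Pknox1, at -1.76, is the 1 gene of the plot with an adjusted p under 0.05, while AY036118 has the largest difference, -2.29.

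Relatives of Prep1 and of its partners did not pass the test where named here. Pbx2 differed by -0.10 (-0.05 without Prep1deltaSM replicate 4), Pbx3 by -0.03 and Pknox2, the paralog of Pknox1, by -0.01. Meis1 differed by 0.30, or 0.06 to 0.40 over the alternative settings. The signs for Pknox2, Pbx2 and Pbx3 turn when the probes of a gene are averaged. Of the 9 members tested of the PBC and MEIS class, 2 were higher and 7 lower, with a median of -0.10 against -0.07 for all genes (camera adjusted p = 0.798). Of 25 Hox genes, 7 were higher and 18 lower (median -0.08, adjusted p = 0.822); Hoxb6 was the 1 past a threshold adjusted over the list alone.

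Gene lists of mitochondrial respiration did not pass the test. Ppargc1a, a coactivator that drives mitochondrial biogenesis, differed by 0.30 ± 0.33 (SE; adjusted p = 0.666), and its relative Ppargc1b by -0.31 ± 0.17 (adjusted p = 0.414). Tfam differed by -0.28, but by -0.08 when its probes are averaged, with its other probes at 0.04 and 0.02. Nrf1 differed by -0.05 and Esrra by -0.10, but by 0.13 and 0.22 when the probes of a gene are averaged. Citrate synthase (Cs) differed by -0.02, and its sign turned with quantile normalization, alone or after normexp. Without Prep1deltaSM replicate 4 the value was -0.05 for Ppargc1a and -0.16 for Ppargc1b. Of 37 complex I genes, 9 were higher and 28 lower (median -0.09 against -0.07 for all genes, camera adjusted p = 0.941). The median was -0.01 for complexes II and III (adjusted p = 0.965), -0.09 for complex IV (0.798) and -0.06 for ATP synthase (0.798), in which Atpif1, an inhibitor of the enzyme, differed by -0.45 and was the 1 gene past a threshold adjusted over the list alone. The median was 0.00 for the TCA cycle (adjusted p = 0.414), -0.08 for mitochondrial fatty acid oxidation (0.979), -0.02 for the regulators of biogenesis (0.798) and -0.05 for the mitochondrial ribosome (0.965). The TCA cycle list passed as higher than other genes with quantile normalization alone (adjusted p = 0.0204) or after normexp (0.001), and without Prep1deltaSM replicate 1 (0.0312); with an estimated correlation its adjusted p was 0.991. The camera direction of complex I, complex IV and ATP synthase turned with quantile normalization, alone or after normexp. That direction is relative to other genes and is not the sign of the list median.

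Glucose metabolism did not pass either. Slc2a4, the insulin-responsive glucose transporter GLUT4, differed by -0.11 ± 0.14 (SE; adjusted p = 0.718), with -0.22 without Prep1f/+ replicate 4, -0.04 without Prep1f/+ replicate 2 and 0.00 with quantile normalization. The median was 0.02 over 21 genes of insulin signalling and glucose uptake (camera adjusted p = 0.193) and -0.05 over 25 genes of glycolysis and glycogen (0.965).

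Fibre type genes did not pass. All 12 slow fibre genes tested were lower in Prep1deltaSM, with a median of -0.42 (camera adjusted p = 0.189, 0.991 with an estimated correlation). The difference was carried by Prep1f/+ replicates 1 and 3, with list means of 0.62 and 0.81, while replicates 2 and 4, at -0.13 and -0.25, lay among the Prep1deltaSM muscles (-0.62 to 0.17), and the list was lower on 3 of the 4 slides. Myl2 differed by -1.93 ± 0.87 (SE), Myh7, the slow myosin, by -1.21 ± 0.88 (-0.57 without Prep1f/+ replicate 3), and myoglobin (Mb) by -0.40 ± 0.15. Myh2 differed by -1.02 ± 0.39 (adjusted p = 0.263), Myh1 by -0.18 and Myh4 by -0.08. The direction for Myh1 depended on the probe, since its other probe differed by 0.58 and the mean of its probes by 0.20, and the sign for Myh4 turned with quantile normalization, alone or after normexp. The 16 fast fibre genes had a median of -0.08 (camera adjusted p = 0.965). The atrophy ligase gene Fbxo32 differed by -0.88 ± 0.25 (adjusted p = 0.193), with its other probe at -0.43. Trim63 differed by 0.25 ± 0.31 (0.712), or -0.10 without Prep1deltaSM replicate 4. Over 21 atrophy genes the median was -0.06 (camera adjusted p = 0.965). Of 20 genes of calcium handling, 11 were higher and 9 lower (median 0.01, 0.189), with Fkbp1a at 0.41, the calcium-binding protein gene Casq1 at 0.36 and the kinase gene Camk2b at -0.30 (-0.40 to -0.09 over the alternative settings). The list passed with quantile normalization alone (0.0204) or after normexp (0.0017), but its adjusted p was 0.991 with an estimated correlation.

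Cytosolic ribosomal protein genes were mostly lower, and formed the 1 list of 33 past the threshold. Of 58 tested, 53 were lower and 5 higher, with a median of -0.14 against -0.07 for all genes (camera adjusted p = 3e-04, but 0.991 with an estimated correlation). Rps14 differed by -0.33, Rps15 by -0.34 and Rps19 by -0.30, while Rpl4 differed by 0.32; 0 members passed an adjusted p of 0.05 over all genes or adjusted over the list alone, and 1 higher and 14 lower members had an unadjusted p under 0.05. The call was also lost with quantile normalization alone (adjusted p = 0.396) or after normexp (0.0848), and with the authors' values (0.589); the list median was then -0.05, -0.06 and -0.04, against -0.03, -0.02 and -0.03 for all genes. The list mean differed by -0.13 (exact two-sided permutation p = 0.0857); with slide as a block the adjusted p was 0.0171, and the list was lower on 3 of the 4 slides, with differences from -0.27 to 0.01.

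**Figure D3:**
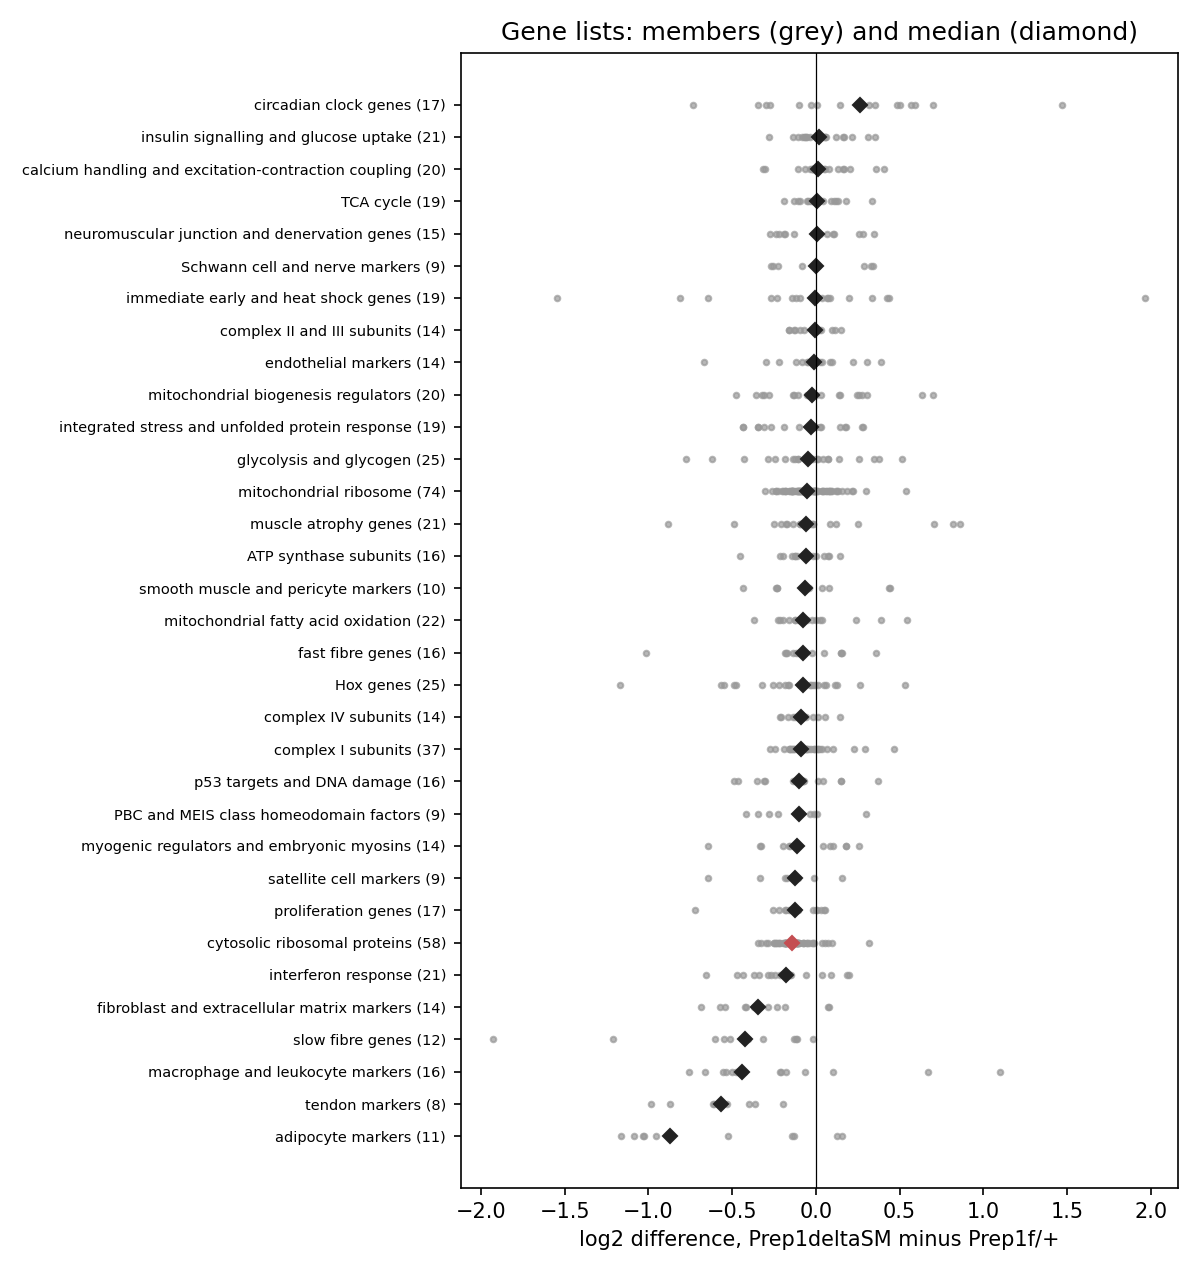
Log2 difference between Prep1deltaSM and Prep1f/+ (x axis) for each member (grey points) and the median (diamond) of the 33 lists tested, with the number of members in brackets. The red diamond marks the ribosomal protein list (median -0.14), the 1 list with a camera adjusted p under 0.05.

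Markers of connective tissue and immune cells were mostly lower in Prep1deltaSM, beside the ribosomal genes, without passing the test. Of 14 fibroblast and matrix markers, 12 were lower (median -0.35, camera adjusted p = 0.157), including Fbn1 at -0.69 and decorin (Dcn) at -0.58, though at 0.05 for Dcn when its probes are averaged. All 8 tendon markers were lower (median -0.57, 0.157), with Chad at -0.98 and Scx at -0.61 (-0.40 without Prep1deltaSM replicate 2). With slide as a block these lists passed (adjusted p = 0.0228 and 0.0322), but with an estimated correlation the adjusted p of every list was 0.991. Both were lower on all 4 slides, and the low values lay in 2 muscles: the fibroblast list mean was -0.35 and -0.64 in Prep1deltaSM replicates 2 and 4, while replicates 1 and 3, at 0.02 and 0.32, lay among the Prep1f/+ muscles (-0.10 to 0.36). The tendon list mean was -0.64 and -1.05 in replicates 2 and 4 and 0.19 and 0.35 in replicates 1 and 3. Both passed without Prep1deltaSM replicate 1 (0.0312 and 0.0219) or replicate 3 (0.000541 and 0.00385), and the fibroblast list without Prep1f/+ replicate 1 (0.0223). Without Prep1deltaSM replicate 4 the adjusted p was 0.592 and 0.529. Of 16 macrophage and leukocyte markers, 13 were lower (median -0.44, 0.193), with the list lower on 2 of the 4 slides. It passed without Prep1deltaSM replicate 3 (0.00385), and without Prep1deltaSM replicate 4 its adjusted p was 0.592. Of 21 interferon response genes, 17 were lower (median -0.18, 0.157), and H2-K1, a class I histocompatibility gene, differed by -0.37 and was past a threshold adjusted over the list alone. H2-K1 and the list members H2-D1, Psmb8 and Psmb9 lie within 5 Mb of Pknox1. The interferon list passed without Prep1deltaSM replicate 2 (0.0494), but not without Prep1deltaSM replicate 4 (0.424). The fibroblast, tendon, leukocyte and interferon lists passed with every probe as its own row (0.0394 each). The adipocyte markers had a median of -0.87 over 11 genes (0.798), with list means of -1.57 and -0.97 in Prep1deltaSM replicates 2 and 4 and 0.72 and 0.61 in replicates 1 and 3. Medians were -0.01 for endothelial (0.798), -0.06 for smooth muscle and pericyte (0.854), 0.00 for Schwann cell and nerve (0.822) and -0.12 for satellite cell markers (0.418); Schwann cell markers passed without Prep1f/+ replicate 3 (0.0098). Of 9 satellite cell markers 8 were lower, and their list mean was the 1 list mean with an exact two-sided permutation p under 0.05 (0.0286, or 0.566 adjusted over lists). Of the erythroid markers 4 were tested, too few for the test.

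Circadian clock genes had a median of 0.26 (camera adjusted p = 0.157), with Cry1 at 0.57 and Cry2 at 0.50. With quantile normalization after normexp these were 0.11 and 0.29, the mean of its probes gave 0.21 for Cry1, and without Prep1f/+ replicates 1 and 4, left out together after the data were seen, Cry2 was at 0.17. In this list the Prep1f/+ muscles were not alike: the list mean of replicate 1 was -0.87, while the other 3 lay between 0.08 and 0.21 and the Prep1deltaSM muscles between 0.00 and 0.22. Without that muscle the adjusted p of the list was 0.907. The remaining lists did not pass: myogenic regulators (median -0.11, adjusted p = 0.882), neuromuscular junction genes (0.00, 0.798), immediate early and heat shock genes (0.00, 0.965), the integrated stress response (-0.03, 0.992), p53 targets (-0.10, 0.965) and proliferation genes (-0.13, 0.804). By fry, which asks whether a list moves one way without comparing it with other genes, the integrated stress response was lower (adjusted p = 0.0284), and was the 1 list past that test. Its median of -0.03 lay above the -0.07 of all genes, an offset that fry does not remove. By camera the direction of this list turned under several settings given below. The mixed form of fry, which asks whether members change in either direction, was passed by 13 lists (adjusted p from 0.000149 to 0.0251): ribosomal proteins, ATP synthase, biogenesis regulators, mitochondrial ribosome, glycolysis, PBC and MEIS factors, Hox genes, myogenic regulators, p53 targets, interferon response, calcium handling, smooth muscle and satellite cell markers. This form does not compare a list with other genes either. Of all 16016 genes, 2541 had an unadjusted limma p under 0.05, where 800.8 are expected by chance. Passing it therefore does not set these lists apart from genes in general.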

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

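The comparison of cell type markers was chosen after its result was seen, and the windows along chromosomes after the test of the genes near Pknox1. In 11 of 200 groups of 4 values, 1 muscle stood apart from the others by Dixon's ratio, where chance gives about 10. In Prep1deltaSM replicate 4 the list mean of the atrophy genes was highest (ratio 0.941), as were Trim63 (0.834) and Hist1h1a (0.914). Uvrag was lowest in Prep1deltaSM replicate 2 (0.865). In Prep1f/+ replicate 1 the list mean of the circadian clock genes was lowest (0.881), and Scn2a1 (0.879) and Psmb8 (0.873) were highest. In Prep1f/+ replicate 3 Mb was lowest (0.888) and the mean of the Schwann cell markers highest (0.86). Complex IV was highest in Prep1f/+ replicate 2 (0.903), and the proliferation genes in Prep1f/+ replicate 4 (0.882).

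Of the 35 splits of the 8 arrays into 4 and 4, 5 gave at least the 1 gene past an adjusted p of 0.05, with 6 genes in the highest other split, so chance is not excluded for that count. For genes with an unadjusted p under 0.01, 1 of the 35 splits, the real one, reached 769, and the highest other split gave 405. That share is under 0.05, the bound set in advance, but it is the smallest that 35 splits can give. Most of these splits do not part the 2 arrays of every slide. Of the 8 that do, as the design does, 1 reached 769 and the highest other gave 170, and 8 are too few for a share under 0.05. Chance was therefore not excluded within the layout of the slides.

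Of 58 ribosomal protein genes, 53 were lower and 5 higher in Prep1deltaSM, with a list call that was lost with an estimated correlation (adjusted p = 0.991). A mean t of the list as far from that of the other genes was found in 2 of 35 splits (1.14 in the real one, 1.18 in the highest other), so chance is not excluded; camera called this list in 14 of the splits, and at least 1 list in all 35, up to 17. A smaller share of every cell type other than muscle fibres stays open. Markers of fibroblasts and leukocytes differed from those of endothelium, Schwann cells and smooth muscle by -0.26 ± 0.23 (SE over mice, exact two-sided permutation p = 0.314). Medians of endothelial, Schwann cell and smooth muscle markers were -0.01, 0.00 and -0.06, none below the -0.07 of all genes. Within Prep1deltaSM the fibroblast and ribosomal lists did not go together. Replicate 4 had the lowest fibroblast list mean (-0.64) and the highest ribosomal one of its group (-0.03), and replicate 1 had 0.02 and -0.12. A shift of abundant transcripts in general also stays open. The ribosomal median lay at percentile 1.88 of random lists matched on expression, whose medians centred on -0.11, between the bounds set in advance. These lists were not matched on correlation between genes, which was estimated at 0.47 within the ribosomal list. The percentile may therefore be too extreme. A shift common to a slide cancels, because each slide held 1 array of each group, so the count of slides cannot decide on it; the list was lower on 3 of 4 where a bound set in advance asked for all 4, and a slide effect unlike in its 2 arrays stays open. A biological effect of Prep1 loss was not separated from these.

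Small p-values gathered near Pknox1 on chromosome 17. Of 231 tested genes within 5 Mb of its probe, 19 had a p under 0.01, 8.23% against 4.69% of other genes (Fisher's exact test, one-sided p = 0.0139); 3 were higher and 16 lower. DNA of another strain beside the targeted allele is a candidate explanation, but Btbd9 prompted the test, and the Fisher p was 0.0253 without it and 0.0748 without it and the H2 genes. General clustering along chromosomes was not excluded: 1.82% of 5444 windows of the same size around other genes held as high a share.

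Transcripts without poly(A) tails, Rmrp, Snord33 and Hist1h1a, were among the smallest p-values. A one-way difference in the labelling of such transcripts stays open. Over 33 histone cluster and small nucleolar RNA genes, taken by name without a check of their tails, the median was -0.05, against -0.07 for all genes. That lay within the bound set in advance against such a difference (camera p = 0.366 in a preset-correlation test). But the median rests on 30 histone genes (median -0.02) that go both ways. The 3 small nucleolar RNAs were all lower, with a median of -0.44 (Snord33 -1.10, Snora3 -0.44 and Snord35b -0.25), as was Rmrp (-1.10). No biological explanation was tested.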

How the results depend on the processing

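Leaving out Prep1f/+ replicates 1 and 4 together was chosen after seeing the data; the other settings were fixed before the data were examined. Pknox1 was lower in Prep1deltaSM under all 21 settings and was past the adjusted threshold under 16 of them, with adjusted p from 0.0018 to 0.0673. It missed the threshold at the unchanged difference of -1.76 with slide as a block (adjusted p = 0.062), where fewer residual degrees of freedom remained, and at -1.78 without Prep1f/+ replicates 1 and 4 together (0.0558), where fewer arrays remained. Leaving out 1 array gave -1.84 to -1.68, and the call was lost without Prep1f/+ replicate 2 (0.0626), Prep1f/+ replicate 3 (0.057) or Prep1deltaSM replicate 2 (0.0673). The processed Pknox1 signal was 39.8 to 170, and an offset of 50 added to each intensity shrinks log2 differences of such dim probes. With normexp at that offset followed by quantile normalization of mean signal, the difference was -0.89. Background correction, offset, normalization and input change together in this setting, and their parts were not told apart. Genes higher numbered 16 with this setting, 7 with the trended robust fit, 12 with array weights and 170 at an unadjusted p under 0.05 with at least 1.5-fold; without 1 array they numbered 0. Genes lower numbered 10, 13, 13 and 339 under these settings, 0 with slide as a block and 0 without Prep1f/+ replicates 1 and 4 together, and 0 to 5 without 1 array. Lists past the threshold numbered 2 with normexp followed by quantile normalization and 2 with quantile normalization alone, 5 with every probe as its own row, 0 with the authors' values, 3 with slide as a block, 0 with an estimated correlation and 1 by the directional and 13 by the mixed fry test, and 1 to 4 without 1 array. The adjusted p of the ribosomal protein list was 0.0848 with normexp followed by quantile normalization, 0.396 with quantile normalization alone, 0.589 with the authors' values, 0.991 with an estimated correlation and 0.219 by fry, and 3.3e-06 to 0.02 without 1 array; the cause was not tested for the counts and lists that changed. Scan date could not be run as a block, since all arrays shared 1 scan day. 

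The sign of a named gene's log2 difference turned with the authors' values for Btbd9 (-0.0109) and Pknox2 (0.0378). The other sign was seen with the mean of a gene's probes for Pknox2 (0.19), Pbx2 (0.00557), Pbx3 (0.027), Nrf1 (0.13), Esrra (0.22), Myh1 (0.20) and Dcn (0.0462). A turned sign was found with normexp followed by quantile normalization for Pknox2 (0.00778), Pbx3 (0.000889), Cs (0.0789), Myh4 (0.039) and Myl3 (0.0301). The log2 difference changed sign with quantile normalization alone for Cs (0.0704), Myh4 (0.0582) and Myl3 (0.00515). The sign of a named gene's log2 difference turned with Prep1f/+ replicates 1 and 4 left out together for Nrf1 (0.00804). For lists, the direction given below is that of camera, relative to other genes, and not the sign of the list median. It turned with array weights for complex II and III subunits (0.904), integrated stress and unfolded protein response (0.98) and proliferation genes (0.905). Lists changed direction with the authors' values for complex I subunits (0.303), complex IV subunits (0.616), ATP synthase subunits (0.592), mitochondrial ribosome (0.326), muscle atrophy genes (0.76) and integrated stress and unfolded protein response (0.889). A list's direction was the opposite one with the trended robust fit for mitochondrial fatty acid oxidation (0.99955) and integrated stress and unfolded protein response (0.914). The opposite direction was found with every probe as its own row for mitochondrial fatty acid oxidation (0.835), mitochondrial ribosome (0.934), fast fibre genes (0.933), neuromuscular junction and denervation genes (0.919), immediate early and heat shock genes (0.768) and Schwann cell and nerve markers (0.934). Fry does not compare a list with other genes, as camera does. By fry the direction was not that of camera for complex II and III subunits (0.96), mitochondrial fatty acid oxidation (0.845), mitochondrial biogenesis regulators (0.994) and glycolysis and glycogen (0.648). The same held for fast fibre genes (0.845), immediate early and heat shock genes (0.845), endothelial markers (0.994) and smooth muscle and pericyte markers (0.994). Both tests used the same values, so no difference turned here. Lists changed direction with the mean of a gene's probes for mitochondrial fatty acid oxidation (0.884), myogenic regulators and embryonic myosins (0.884) and immediate early and heat shock genes (0.884). A list's direction was the opposite one with no filter for complex I subunits (0.869), mitochondrial ribosome (0.751), muscle atrophy genes (0.869), integrated stress and unfolded protein response (0.783) and proliferation genes (0.869). The opposite direction was found with normexp followed by quantile normalization for complex I subunits (0.0848), complex IV subunits (0.754), ATP synthase subunits (0.291), mitochondrial ribosome (0.0848), muscle atrophy genes (0.912), immediate early and heat shock genes (0.912) and integrated stress and unfolded protein response (0.912). The direction turned with quantile normalization alone for complex I subunits (0.123), complex IV subunits (0.48), ATP synthase subunits (0.385), mitochondrial ribosome (0.12), muscle atrophy genes (0.969) and immediate early and heat shock genes (0.969). With slide as a block the median difference of all genes stayed at -0.07, since each slide held 1 array of each group. Only the camera direction relative to other genes turned, for mitochondrial ribosome (0.938) and muscle atrophy genes (0.996). A list's direction was the opposite one with the filter on all 8 arrays for mitochondrial ribosome (0.974), immediate early and heat shock genes (0.974) and integrated stress and unfolded protein response (0.974). The opposite direction was found with Prep1f/+ replicates 1 and 4 left out together for mitochondrial ribosome (0.785), myogenic regulators and embryonic myosins (0.974), integrated stress and unfolded protein response (0.916), proliferation genes (0.785) and Schwann cell and nerve markers (0.785). Leaving out 1 array at a time, the log2 difference ranged over both signs for Pknox2 (-0.0871 to 0.0659), Pbx3 (-0.0747 to 0.00613), Ppargc1a (-0.0515 to 0.50), Nrf1 (-0.16 to 0.0124), Cs (-0.0584 to 0.0455), Myh4 (-0.14 to 0.00185) and Trim63 (-0.0965 to 0.39). The adjusted p of lists that turned in some of these runs ranged as follows, for complex I subunits (0.299 to 0.941), complex II and III subunits (0.193 to 0.943), complex IV subunits (0.368 to 0.944), ATP synthase subunits (0.35 to 0.938), mitochondrial fatty acid oxidation (0.207 to 0.943), mitochondrial ribosome (0.218 to 0.941), glycolysis and glycogen (0.725 to 0.943), fast fibre genes (0.645 to 0.975), myogenic regulators and embryonic myosins (0.724 to 0.97), muscle atrophy genes (0.352 to 0.941), immediate early and heat shock genes (0.199 to 0.941), integrated stress and unfolded protein response (0.938 to 0.999), p53 targets and DNA damage (0.725 to 0.967), proliferation genes (0.218 to 0.943), adipocyte markers (0.184 to 0.943), endothelial markers (0.38 to 0.997) and Schwann cell and nerve markers (0.0098 to 0.967). The lists that turned did not pass the threshold in the turned direction. For Btbd9 the authors' values come from another probe of the gene. Spots well above background numbered 23787 to 27123 per array, and dim probes limit the precision of the values.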

Other observations

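The genes discussed here were chosen after their values were seen. On the chromosome that holds Pknox1 (17, mm9), some genes on one side of it had higher signal in Prep1deltaSM without passing an adjusted p of 0.05 by limma. Among them were Btbd9, at 0.83 ± 0.10 (SE, adjusted p = 0.0897) for the probe from 30650529 to 30650588, and Glo1 at 0.32 ± 0.08 (0.166) for the probe from 30729951 to 30730010. Dnahc8, between Glo1 and Pknox1, was at 0.78 for the probe from 31012058 to 31012117, which was well above background on 5 of the 8 arrays. Other Dnahc8 probes, at -0.29 and -0.60, were well above background on 0 arrays. On the same side Mdga1 was lower, by -0.51, for the probe from 29969255 to 29969314. Within 5 Mb of the Pknox1 probe, 3 genes with an unadjusted limma p under 0.01 were higher and 16 lower. Several probes around Btbd9 and Glo1 did not share the difference. The gene 0710001D07Rik, between Btbd9 and Glo1, differed by 0.10, the Glo1 probe from 30731070 to 30731129 by 0.12, and Btbd9 probes farther from Glo1 by -0.01 and 0.16. Of the tested genes near Pknox1, Abcg1, Tmprss3, Slc37a1, Pde9a, Wdr4, Ndufv3 and U2af1 differed by -0.23 to 0.22. That range does not cover other tested genes nearby.

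Several lists held single genes past a threshold adjusted over the list alone whose list did not shift. The immediate early genes Junb and Ier2 differed by -0.65 and -0.81, and Bax, a p53 target, by 0.37. Among smooth muscle markers Acta2 and Myh11 differed by 0.44 each and Cspg4 by -0.44. These genes had adjusted p-values of 0.129 to 0.221 over all genes by limma.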
